A study of Mus musculus with 6 samples.

How the data were processed

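Soleus muscle of C57Bl/6 mice was profiled on expression arrays after 1 day of reloading, with 1 array for each of 6 wild-type samples (so titled). Per the labels, RNA came from cryosections and 3 micrograms of total RNA per sample went into the array analysis. The labels gave every sample the same group and numbered the replicates 1 to 6. They did not state that the 6 samples came from 6 animals, so every spread below is between these samples and can include technical differences. The p-values over pairings of samples rest on this spread. Those over random gene lists or spot positions permute genes or spots and do not measure it. No unloaded or untouched control muscle was analysed here, and no comparison between conditions was made.

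The deposited table held 1 intensity per probe and array for 223 probes, with no missing values. The scanner, the array type, the background method and the normalization were not given in the sources used here. The deposited intensities were on a linear scale and went as low as -0.0144 on replicate 1, so some background had been subtracted from them. Summed over all probes they came to 165.3 on replicate 1, between 35.2 and 41.3 on replicates 2 to 5, and 13.8 on replicate 6, so the arrays had not been brought to a common total. The deposited values of the 28S ribosomal RNA probe were whole hundredths, to all decimals given, on all 6 arrays, which held for 0 of the other probes. Whether that probe was measured in the same way as the others is not known, which limits every value scaled to 28S. No pair of arrays held identical values.

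Probes were named from the platform annotation of the series. It listed 205 of the 223 probes with 1 gene each, and 18 probes stayed unnamed. Gene identifiers of 204 probes matched a current mouse gene of the GRCm38.p6 gene table, with 0 changes of symbol. The remaining probe was annotated with a human gene symbol and was not above 0 on all arrays. Fn1 and Igf1 had 2 probes each, and the probe with the higher mean intensity stood for the gene. Genomic positions are not given, because the annotation ties the probes to accessions and not to a genome build.

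Probes above 0 on all 6 arrays were kept, which left 175 probes and 162 named genes. Intensities were converted to log2 and each array was centred on the median of these 175 probes. No pseudocount was added. A value of 0 therefore means the median kept probe of that array, and a difference in level between probes is not read as a difference in transcript abundance. The size of the most negative value of each array was used as a bound on background noise. It was 0.0144 on replicate 1 and between 0.0011 and 0.0028 on the others, and 130 probes exceeded it on all 6 arrays. Where a gene was at or under the bound on an array, its fold between the highest and lowest array is given as a bounded range, with such arrays set to the bound and no further allowance for noise. Means, SDs and ranges are on the median-centred scale unless another is named. The number of arrays limits the precision of every mean.

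The values are intensities and not ratios to a reference, so the planned test of mean log ratios against 0 was not run. Before the data were examined, 19 gene lists were fixed, 9 of which had at least 3 members above 0 on all arrays. The untested lists were slow contractile, developmental or cardiac-type contractile, cell adhesion and cytoskeleton, immediate early, heat shock and oxidative stress, proteolysis, and markers of inflammatory and myeloid, neural, adipocyte and blood cells. For each tested list, the median SD of its members and the mean pairwise Pearson correlation of its members over the 6 arrays were placed among 10000 random lists of the same size, drawn within 5 bins of mean level, which is a permutation of genes. The gene permutation p-values of this placement were two-sided and were adjusted over the 9 lists by Benjamini and Hochberg. Genes are not independent replicates, so they describe these arrays. Of 8 planned pairs of lists, 5 were tested, and the others held a list with too few members. For these, list scores (the mean of standardized members, without genes on both lists) were correlated over the 6 arrays with an exact two-sided permutation test over all 720 pairings, adjusted over the 5 pairs. The place of each r among 10000 pairs of random lists was added after the data had been seen.

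The text names, in each tested list, the 2 genes with the largest and the 2 with the smallest SD, and over all 162 genes the 10 largest and the 10 smallest. This rule was also fixed before the data were examined. It covered 49 genes. Any other gene is named as a member of a list too small to test, as a gene with 2 probes, or as chosen after its values were seen.

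The list tests were tested on simulated data, in 100 data sets of 162 genes on 6 arrays. Lists of 10 genes with doubled SD were called in 98.0% of data sets, and lists with a true correlation of 0.5 in 84.0%. Unchanged lists were called in 0.857% by the spread test and in 1.00% by the correlation test. In the simulations, genes without the shared factor varied independently, and every list had 10 genes. The real lists held 3 to 13 genes, and the first principal component held 67.1% of the variance between arrays. These rates therefore do not give the power of the tests on the real lists. Alternatives covered no centring, quantile normalization, other probe filters, a pseudocount of 0.00143, rank correlations, unmatched random lists and leaving out each replicate. Other alternatives were added after the data had been seen, namely a filter at the noise bound, scaling to 28S, leaving out replicates 1 and 6 together, and removing the first principal component. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.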

Results

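Gene expression was measured in the soleus, a postural hindlimb muscle, of mice whose muscle had been reloaded for 1 day. The data consisted of 6 arrays of 223 probes from a single group, replicates 1 to 6. With no second group, the measurements give the level of each gene in reloaded soleus, its spread between samples, and how far genes of one kind moved together from sample to sample.

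The slow and fast myosin genes exceeded the noise bound on every array, while some cytokine and cell division genes were at or below 0 on most arrays. Of the 223 probes, 175 were above 0 on all 6 arrays, 43 on some of them and 5 on none. The interleukin gene Il1b was above 0 on 0 of 6 arrays, and Il6 on 1 of 6. Among members of larger lists, chosen after their values were seen, Ccna2, a cyclin of dividing cells, was above 0 on 1 of 6 arrays, and Top2a, a topoisomerase of dividing cells, on 2 of 6, with 0.0084 in deposited units on replicate 6, above the noise bound of 0.0011. Myf5, an early myogenic factor, was above 0 on 5 of 6 arrays, but its values lay between -0.0001 and 0.0146 in deposited units. Values at or under the noise bound do not show that a transcript was absent.

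The 6 arrays gave similar profiles across genes. The Pearson correlation of log2 intensities had a median of 0.91 over the 15 array pairs and ranged from 0.70 to 0.95. Spearman's rho had a median of 0.90 and ranged from 0.62 to 0.95. These correlations are across genes within pairs of samples, and genes are not independent replicates. Replicate 6 had the lowest median correlation with the other arrays, 0.84, followed by replicate 1 at 0.88. These were also the arrays with the lowest and the highest summed intensity, 13.8 and 165.3, an 11.9-fold difference. After centring, the first principal component held 67.1% of the variance between arrays. Replicate 1 scored -0.66 on it and replicate 6 scored 0.64, with replicates 2 to 5 at -0.12, -0.21, 0.05 and 0.30.

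**Figure D1:**
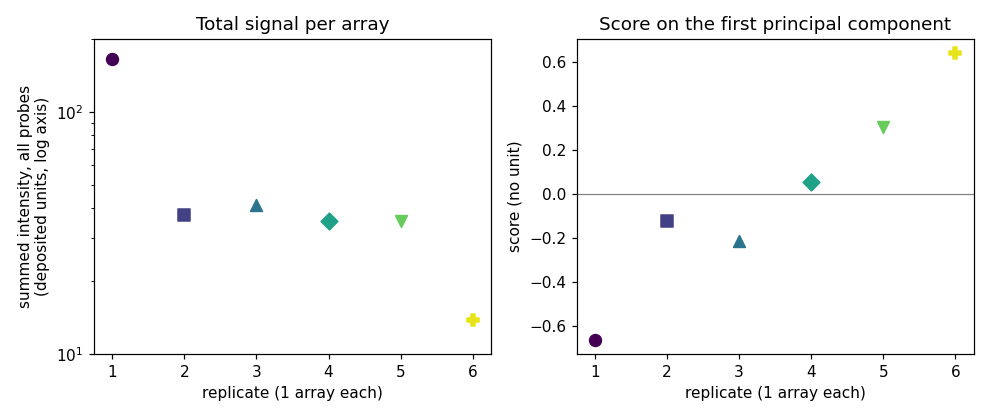
Left, summed intensity of all 223 probes per array in deposited units on a log axis; right, the score of each array on the first principal component of the centred log2 intensities. Each point is 1 array. Replicate 1 had the highest total (165.3) and the lowest score (-0.66), and replicate 6 the lowest total (13.8) and the highest score (0.64).

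After median centring, the 10 genes with the most even levels between samples ranged 1.27-fold to 1.69-fold. The same 10 ranged 1.28-fold to 1.73-fold after quantile normalization. In deposited units they ranged 5.57-fold to 9.95-fold, and after scaling to 28S 2.92-fold to 4.68-fold. Jun, a subunit of the AP-1 transcription factor, had a normalized log2 intensity of 2.35 ± 0.15 (SD, n = 6), a 1.31-fold range between the lowest and highest array. Itgb5, an integrin chain, stood at -0.13 ± 0.14, and Pdgfrb, a receptor for platelet-derived growth factor, at 0.32 ± 0.15. Rpsa, a ribosomal protein and laminin receptor gene, was at -0.77 ± 0.19. Kdr, the main VEGF receptor of endothelium, was at 0.30 ± 0.19, and Ucp3, a mitochondrial carrier of muscle, at 0.61 ± 0.21. The growth factor Tgfb1, the glycolytic enzyme Pgk1, the matrix protein Tnxb and the fatty acid carrier Fabp3 completed the 10 lowest, with SDs from 0.23 to 0.27. Over all 175 probes the median SD was 0.64 log2 units, equal to a 1.56-fold change, and the middle 50% of probes lay between 0.49 and 0.96. The ranking depended on the scaling: the 10 genes of smallest SD shared 5 genes with the 10 after quantile normalization (Itgb5, Kdr, Pdgfrb, Rpsa and Tgfb1), 0 in deposited units and 0 after scaling to 28S.

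The genes with the widest spread were mostly dim on at least 1 array. Cyct, the testis form of cytochrome c, had an SD of 3.54, but a range of 4.90-fold once the array under the noise bound was set to that bound. Agtr2, an angiotensin receptor, had an SD of 2.31 and a bounded range of 27.9-fold, and the laminin chain Lama3 an SD of 2.09 and a bounded range of 24.8-fold. Fosl1, an AP-1 subunit, had an SD of 2.17 and a bounded range of 10.4-fold. With noise of the size of the bound allowed for in both arrays compared, the folds left were 2.29 for Cyct, 13.7 for Agtr2, 12.7 for Lama3 and 4.21 for Fosl1. The integrin chain Itga8, the plasminogen gene Plg, the urokinase receptor Plaur and the VEGF receptor Flt4 had SDs between 1.39 and 1.59, each with at least 1 array at or under the bound. Only 2 of these 10 genes exceeded the bound on all 6 arrays. Ang, the angiogenin gene, ranged 20.2-fold (SD 1.54), but 4.36-fold in deposited units and 6.58-fold after scaling to 28S. Myod1, a myogenic transcription factor, ranged 11.2-fold (SD 1.39), and 51.7-fold in deposited units and 24.3-fold after scaling to 28S, and was lowest in replicate 6. The 10 genes of largest SD shared 7 with the 10 after quantile normalization, 4 with those in deposited units and 5 with those after scaling to 28S. Probes of the upper level range had a median SD of 0.59, and those of the lower range 0.81.

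**Figure D2:**
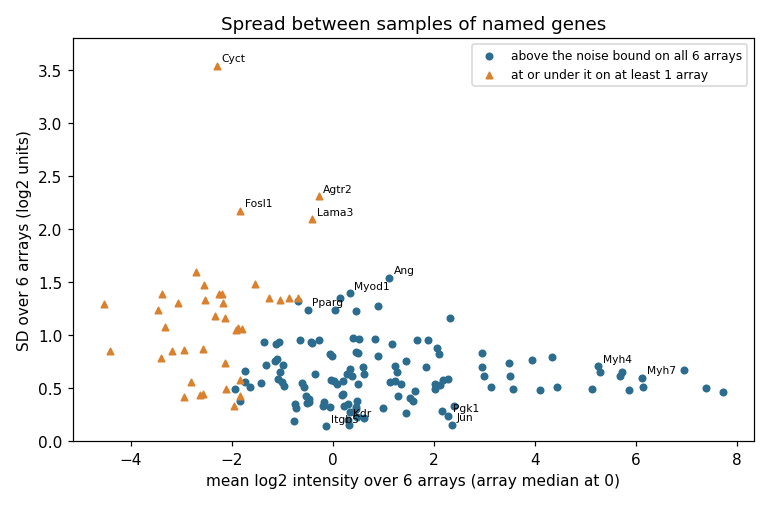
SD over 6 arrays (log2 units) against mean log2 intensity, with the array median at 0, for the 162 named genes, 1 point each. Triangles mark genes at or under the noise bound on at least 1 array; 8 of the 10 genes with the largest SD are among them.

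Which sample held the highest value of a gene depended on how the arrays were scaled. With each array centred on its median, 47 of the 162 genes were highest in replicate 1, 34 in replicate 6 and 35 in replicate 3. In deposited units 137 of them were highest in replicate 1, and after scaling to 28S ribosomal RNA 107 were. The 107 include the 28S gene itself, which is constant on that scale and was assigned to replicate 1. Lowest values gathered in replicate 6, for 76 of the 162 genes under median centring and 111 in deposited units. After quantile normalization it held 54 of the lowest values, and after scaling to 28S 86. A lowest value in replicate 6 is therefore no particular trait of a gene named below. Unless said otherwise, the highest and lowest samples named for single genes held under median centring, in deposited units, after quantile normalization and after scaling to 28S.

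The contractile genes were measured well above background on every array. Myh7, the slow myosin heavy chain of type I fibres and the only measured member of the slow list, was at 6.12 ± 0.60 (SD, n = 6). The fast list held Myh2 (type IIa myosin, 4.10 ± 0.48), Myh1 (type IIx, 5.69 ± 0.62) and Myh4 (type IIb, 5.25 ± 0.70). On the median-centred scale replicate 6 held the lowest value of 76 of the 162 genes, Myh7 among them. All 3 fast myosins were also lowest there, with ranges of 2.51-fold, 3.29-fold and 3.94-fold. After quantile normalization their lowest values fell in replicates 5, 3 and 1. Their mean pairwise correlation over the 6 arrays was 0.85, against a median of 0.48 for random lists of the same level (percentile 85.3, adjusted gene permutation p = 0.89), and it was -0.23 after quantile normalization. Without replicate 3 it was 0.97 (percentile 99.7, adjusted gene permutation p = 0.054). With the first principal component removed it was 0.24 (percentile 48.4). Their median SD of 0.62 lay at percentile 68.9 (adjusted gene permutation p = 0.97). Of genes on lists too small to test, the intermediate filament gene Des was at 5.12 ± 0.49 and the integrin chain Itgb1 at 3.48 ± 0.74.

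Genes of fatty acid and glucose use held some of the most even levels, and the fatty acid list also held some wide ranges. Of 10 fatty acid genes, 6 had an SD under 0.5, among them Fabp3 (0.34 ± 0.27) and the beta-oxidation enzyme Hadh (2.16 ± 0.28). The medium-chain dehydrogenase Acadm ranged 6.08-fold, with its lowest value in replicate 6. Pparg, a regulator of fat cells, had an SD of 1.24 and was highest in replicate 6. The list's median SD was 0.46, against 0.59 for random lists (percentile 5.26, adjusted gene permutation p = 0.32). That percentile was 35.9 in deposited units, 17.8 after quantile normalization and 41.4 after scaling to 28S. Of 10 glucose genes, 4 had an SD under 0.5, including Pgk1 (2.28 ± 0.24) and the glucose transporter Slc2a1 (-0.48 ± 0.37), and the list's median SD of 0.50 lay at percentile 4.93 (adjusted gene permutation p = 0.32). For glucose genes the percentile was 40.6 in deposited units and 4.2 after quantile normalization. The lactate dehydrogenase gene Ldha ranged 4.04-fold, and the insulin receptor gene Insr 2.59-fold when bounded. Among 6 mitochondrial genes, Ucp3 and the cytochrome oxidase subunit Cox6a2 (6.15 ± 0.51) varied least. Cox5b, another subunit, ranged 5.13-fold, and Tfam, a mitochondrial transcription factor, was above the noise bound on 3 of 6 arrays. This list's median SD of 0.64 was at percentile 66.3 (adjusted gene permutation p = 0.97).

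Scores of the mitochondrial and the glucose lists rose and fell together over the 6 samples. Pearson's r was 0.93 (exact permutation p = 0.00694, adjusted p = 0.028) and Spearman's rho 0.94 (exact permutation p = 0.0167, adjusted p = 0.083). Without replicates 1 and 6, the samples farthest from the median, r was 0.99. The mitochondrial and fatty acid scores had r = 0.86 (exact permutation p = 0.028, adjusted p = 0.046) and rho = 0.71 (exact permutation p = 0.136, adjusted p = 0.227). That relation rested on replicates 1 and 6, since r was 0.33 without them, and 0.57 without replicate 6 alone. Random pairs of lists of the same sizes and levels had a median r of 0.75 and 0.70, and the observed values lay at percentiles 89.1 and 76.6 of them. Neither relation exceeded the 95th percentile of random pairs, 0.96 and 0.95. After quantile normalization neither passed the threshold (r = 0.83 and 0.80, adjusted exact permutation p = 0.086 for both). Within the lists, the mean r was 0.37 for glucose genes, against a median of 0.099 for random lists (percentile 90.8, adjusted gene permutation p = 0.89), which did not pass the threshold. It was 0.14 for mitochondrial genes against 0.14, and 0.067 for fatty acid genes against 0.068 (adjusted gene permutation p = 1.00 for both). In deposited units the mean r was 0.85 for glucose, 0.65 for mitochondrial and 0.75 for fatty acid genes. Random lists were also more correlated on that scale, and these values lay at percentiles 86.8, 43.4 and 71.1 of them. After quantile normalization the mean r was 0.31, -0.0052 and 0.061. With only probes above the noise bound, which left 5 of the 6 mitochondrial genes and dropped Tfam, the mitochondrial value was 0.57. It lay at percentile 84.9 (adjusted gene permutation p = 0.61).

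Among the 6 myogenic regulators, the muscle transcription factors differed in how evenly they were expressed. Mef2a varied least (-0.53 ± 0.42), followed by Myog, the factor of terminal differentiation (0.014 ± 0.56, a 2.61-fold range). Myf6, the myogenic factor of mature fibres, ranged 4.12-fold and was lowest in replicate 6, as was Myod1. Of 5 cell cycle genes, the retinoblastoma gene Rb1 (0.21 ± 0.33) and the cyclin Ccnd1 (-0.045 ± 0.57) varied least. The cell cycle inhibitor Cdkn1a had a bounded range of 16.1-fold and was highest in replicate 1, whereas the kinase gene Cdk4 ranged 10.6-fold and was highest in replicate 6. The median SDs of the myogenic and cell cycle lists, 0.63 and 0.59, lay at percentiles 60.7 and 43.6 (adjusted gene permutation p = 0.97 for both). Their mean correlations within the list were 0.17 and -0.093 (adjusted gene permutation p = 0.89 for both). In deposited units these were 0.77 and 0.46, at percentiles 62.9 and 38.4 of random lists on that scale. After scaling to 28S they were 0.62 and 0.23, at percentiles 61.35 and 27.6. The scores of the 2 lists had r = 0.91 (exact permutation p = 0.0111, adjusted p = 0.028) and rho = 0.89 (exact permutation p = 0.033, adjusted p = 0.083). Without replicates 5 and 6, the farthest from the median, r was 0.98. Random pairs of lists had a median r of 0.36, and 96.5% of them had a lower r. With only probes above the noise bound, r was 0.68 (adjusted exact permutation p = 0.14), and after quantile normalization it was 0.84 (adjusted exact permutation p = 0.086). In all, 3 of the 5 pairs of lists tested passed by Pearson's r and 0 by Spearman's rho after adjustment.

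Matrix, growth factor and vascular genes each held members that were higher toward either end of the array scores. Of 13 matrix genes, the protease gene Plau (-1.84 ± 0.42) and the protease inhibitor Timp1 (0.19 ± 0.44) varied least. The laminin chain Lamc1 ranged 5.67-fold and was highest in replicate 1, and the gelatinase Mmp2 had a bounded range of 5.12-fold and was highest in replicate 6. Of 13 genes of growth factors, receptors and binding proteins, Tgfb1 (0.47 ± 0.23) and the IGF-binding protein Igfbp4 (-0.73 ± 0.31) varied least. Igfbp2 had a bounded range of 3.57-fold, and the receptor Igf1r was above the noise bound on 3 of 6 arrays. Of 11 vascular genes, 7 had an SD under 0.5, including Kdr and the angiotensin-converting enzyme Ace (0.46 ± 0.30). The VEGF receptor Flt1 ranged 5.60-fold, but 1.78-fold in deposited units and 2.17-fold after scaling to 28S. The ligand Angpt2 ranged 4.97-fold, with 4.62-fold in deposited units and 6.24-fold after scaling to 28S.

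After median centring, vascular genes had a median SD of 0.40, against 0.63 for random lists. That was at percentile 1.28 (gene permutation p = 0.029) and did not pass adjustment (adjusted p = 0.26). The percentile was 31.2 in deposited units, 8.18 after quantile normalization and 10.1 after scaling to 28S, and in each of these another list lay lower. Matrix genes (0.67, percentile 47.7, adjusted gene permutation p = 0.97) and growth factor genes (0.53, percentile 11.3, adjusted p = 0.54) did not stand apart either. Mean correlations within the vascular, matrix and growth factor lists were 0.096, 0.11 and 0.022 (adjusted gene permutation p = 0.89, 0.89 and 1.00). In deposited units they were 0.74, 0.61 and 0.47, at percentiles 84.9, 77.9 and 33.9 of random lists on that scale. Over all alternatives they went down to -0.055, 0.051 and -0.048. In all, 0 of 9 lists passed the adjusted threshold of 0.05 for spread, with 1 at an unadjusted p under it, and 0 of 9 for correlation within the list, with 0 at an unadjusted p under it. The scores of matrix and vascular genes had r = 0.19 (exact permutation p = 0.764, adjusted p = 0.764), rho = 0.086 (exact permutation p = 0.919, adjusted p = 0.919), and r = -0.51 without replicates 3 and 4. Those of growth factor and matrix genes had r = 0.55 (exact permutation p = 0.267, adjusted p = 0.333) and rho = 0.60 (exact permutation p = 0.242, adjusted p = 0.302). Without replicates 1 and 5 that r was 0.91. These p-values miss the threshold in a design of 6 samples and do not show that the lists were unrelated.

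**Figure D3:**
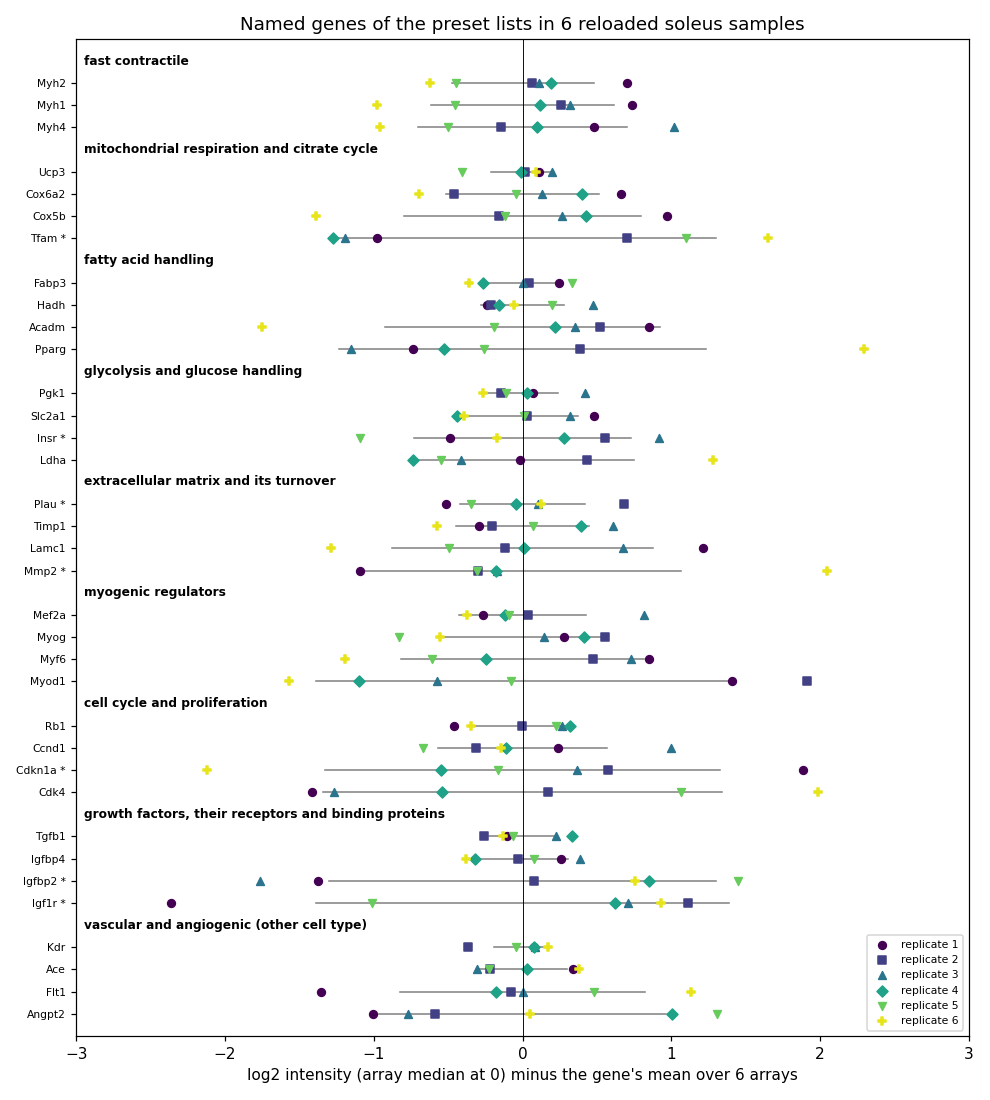
Normalized log2 intensity minus the gene's own mean for the named genes of the 9 tested lists, 1 symbol per replicate, with grey lines of 1 SD on either side of the mean (n = 6). Asterisks mark genes at or under the noise bound on at least 1 array. On this scale replicate 6 is lowest for 76 of the 162 named genes. The 3 fast myosins are among them, though not after quantile normalization. On the scale shown, Myod1, Cdkn1a and Pparg spread more widely than Kdr, Tgfb1 and Pgk1.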

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

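The tests of overall signal, of closeness to background and of the 2 Igf1 probes (given with the other observations) were chosen after the results had been seen; those of brightness and position were not. Among 63 sets of 6 values, 5 held a sample whose gap to the next exceeded 0.625 of the whole range. Gene values and list scores were taken on the median-centred log2 scale. The summed intensity was taken in linear deposited units, and its gap on a log2 scale was not tested. Chance would give about 3.15 for normal values in sets not chosen by their spread. Here 49 sets were genes chosen by their SD in these same values, so that rate does not apply directly. The summed intensity of replicate 1, 165.3, lay far above the other arrays (13.8 to 41.3). Cyct was at -9.34 log2 units in replicate 1, against -1.94 to 0.13 in the others, and its value there was 0.0001 in deposited units. Mef2a was highest in replicate 3, at 0.29, against -0.90 to -0.49 elsewhere, but replicate 1 was highest in deposited units and after scaling to 28S. Mmp2 was highest in replicate 6, at 0.17, against -2.98 to -2.06. Ucp3 was lowest in replicate 5, at 0.20, against 0.60 to 0.81, but replicate 6 was lowest in deposited units.

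The first pattern weighed was the single axis that held 67.1% of the variance between the 6 arrays, along which Myh1, Itgb1, Dmpk, Acadl, Lamc1 and Cd44 went one way, and Egf, Agtr2, Ang, Flt1, Efnb2 and Ghr the other (genes chosen after their values were seen). The axis kept 62.7% of the variance after quantile normalization (95% interval over resampled probes 55.8 to 69.7). This argues against a response that depends on probe brightness as the whole cause. A part in it stays open, since probe correlations with the axis had rho = -0.24 with mean level. A position effect stays open: adjacent spots resembled each other in their correlation with the axis (Moran's I = 0.174 against a mean of -0.0072 and SD of 0.073 in 10000 permuted layouts, one-sided permutation p = 0.0071). This also held with neighbours left out whose gene symbols begin with the same letters (I = 0.171, permutation p = 0.0128). The layout also places genes of one function together, and those with unlike symbols were not left out. Overall signal stays open too, since scores had r = -0.833 with the log2 median intensity of the arrays (exact permutation p = 0.054) and rho = -0.49 (exact permutation p = 0.356), with r = 0.92 in the opposite direction without replicates 1 and 6, whereas with log2 summed intensity they had r = -0.93 (exact permutation p = 0.00278), rho = -0.94 (exact permutation p = 0.0167) and r = -0.80 without the same replicates. The design names no biological difference between the samples, so no biological explanation was tested.

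The second pattern was the wide spread, after median centring, of 10 genes, 8 of which had an array at or under the noise bound. Each gene was tested by the largest fold left between 2 arrays once noise of the size of the bound was allowed for in both. The fold left was 13.7 for Agtr2, 12.7 for Lama3, 12.5 for Ang, 8.59 for Myod1, 5.86 for Itga8 and 4.21 for Fosl1, each above the 3.32-fold range of the median gene, which argues against noise of that size as the whole cause of their spread. It was 2.29 for Cyct, 1.60 for Flt4, 1.479 for Plg and 1.08 for Plaur, so background noise stays open for these 4. The scaling between arrays stays open as well, since the 10 genes of largest SD shared 7 of these after quantile normalization, 5 after scaling to 28S and 4 in deposited units (Cyct and Fosl1 in all), and no biological explanation was tested.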

How the results depend on the processing

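The noise bound, the 28S scaling, leaving out replicates 1 and 6 together and removing the first principal component were chosen after the data had been seen. The counts of lists called for spread and for correlation within the list stayed at 0 under every alternative run, and the median correlation between arrays stayed between 0.90 and 0.95. The median SD of 0.64 became 1.15 in deposited units, 1.00 after scaling to 28S and 0.47 without replicates 1 and 6. Deposited units and the 28S scaling leave differences in overall signal in place. Divided by 28S, summed intensity still ran from 7.69 on replicate 6 to 43.2 on replicate 1. The cause of the value without replicates 1 and 6 was not tested. The median SD ranged from 0.53 to 0.70 when 1 replicate was left out. The number of related list pairs, 3 of 5, changed most. It was 5 in deposited units and 5 after scaling to 28S, and on both scales differences in overall signal enter every score. It was 0 after quantile normalization, 0 among the 87 probes of highest mean level (4 pairs) and 0 by Spearman's rho, and 1 (mitochondrial with glucose genes, r = 0.96) above the noise bound; the cause was not tested. The r of mitochondrial with glucose genes was 0.83 after quantile normalization and 0.92 to 0.98 when 1 replicate was left out, that of mitochondrial with fatty acid genes 0.80 and 0.57 to 0.95, and that of myogenic with cell cycle genes 0.84 and 0.80 to 0.92. With scores standardized anew over the 4 samples left without replicates 1 and 6, these were 0.97, 0.16 and 0.79, whereas scores standardized over all 6 samples gave 0.99 and 0.33 for the pairs with mitochondrial genes. The highest adjusted p of each over the alternatives was 0.089, 0.41 and 0.14. Growth factor and matrix scores, at r = 0.55, had r = -0.32 without replicates 1 and 6, and matrix and vascular scores, at 0.19, had r = -0.44 among the brightest probes. The alternatives with 4 or 5 samples gave r without a test. The myogenic and cell cycle pair had too few members among the brightest probes, and mean log ratios against 0 were not tested in any way, since the values are not ratios. Dim probes limit how far the widest spreads can be read, since 130 of the 175 probes exceeded the noise bound on all 6 arrays.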

Other observations

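The test of the Igf1 probes was chosen after the results had been seen. Several more genes describe the reloaded muscle (Mb, Ttn, Il6st, Igf2, Tnc and Fosl2 were chosen after their values were seen, and the others are members of lists too small to test). Myoglobin (Mb, the oxygen store of muscle fibres) was at 5.86 ± 0.48 log2 units (SD, n = 6) and titin (Ttn, the elastic protein of the sarcomere) at 5.29 ± 0.65. Tnc, the gene of the matrix protein tenascin-C, was above the noise bound on 6 of 6 arrays at 0.59 ± 0.69. Hmox1, the inducible haem oxygenase, was at 0.46 ± 1.22, highest in replicate 1 and lowest in replicate 6. Of AP-1 subunits, Jund was at 0.62 ± 0.63 and Fosl2 at 0.38 ± 0.62, while Junb was above 0 on 2 of 6 arrays. Il6st, the shared signalling chain of interleukin-6 type receptors, ranged 4.25-fold, and Igf2, a growth factor, 8.99-fold. The muscle protease Capn3 was above the noise bound on 2 of 6 arrays, and the calpain inhibitor Cast was at 0.20 ± 0.56. Of the adipocyte list, Fabp4 and Pparg were measured on all arrays and Lipe was above 0 on 2 of 6. Of the inflammatory list, Nos2 was above 0 on 5 of 6. The developmental contractile, neural and blood lists had 0 genes among the named probes.

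The gene Igf1, a growth factor for muscle, had 2 probes of different accessions, which allowed a hypothesis to be tested. If samples differed in Igf1 transcript, both probes may be expected to move together. Their values had r = 0.881 over the 6 arrays (exact permutation p = 0.028) and rho = 0.83 (exact permutation p = 0.058), and r = 0.81 after the first principal component was removed. On the median-centred scale both were highest in replicate 5, at 2.64 and 2.86 log2 units. Their ranges differed, at 13.1-fold and 4.48-fold, and in replicate 1 they stood at -1.07 and 0.69. The relation rested in part on replicates 1 and 5, since r was 0.44 without them. The 2 probes of Fn1 (fibronectin) share an accession in the annotation, yet 1 was above the noise bound on 6 of 6 arrays (0.0256 to 0.3041 in deposited units) and the other on 3 of 6 (-0.0009 to 0.0050).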
